A study of Mus musculus with 8 samples.

How the data were processed

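The 8 samples were 10x Visium sections of fresh-frozen mouse hindpaw, from 2 biological replicates at each of 4 times (uninjured, and 14, 21 and 28 days after tendon surgery). Per the labels, whole hindpaws were collected and sectioned onto the capture slides, and libraries followed the manufacturer's user guide. Per the submitters' processing notes, Space Ranger 1.3.1 and Cell Ranger were used with the mm10 mouse genome. Per the file headers, the matrices of D0 replicate 1, both D14 replicates and D28 replicate 1 were written by version 1.1.0 of Space Ranger and the other 4 by version 1.3.1. The authors deposited for each section raw UMI counts per gene and spot, which are not normalized, with the position of each spot and a list of the barcodes that form the region of interest (ROI). How the ROI was drawn and on what basis is not given in the sources used here, so a gene seen by the authors while drawing it would be no independent finding.

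The matrices held 32286 features. The feature named Tdtomato is the transcript of the Ai9 reporter and lies outside the mouse genome. Gene coordinates were taken from GENCODE M21 on mm10, in which 32235 of the feature identifiers were found, 31502 of them with the same symbol; 78 symbols were shared by more than 1 identifier. The deposited spots were those over tissue. No doublet caller and no deconvolution was run, since a spot can hold several cells. For each section the counts were summed over the ROI spots and, separately, over the remaining spots, so that each section gave 1 library per region and the animal, not the spot, was the replicate. Sections of 1 group differed by far more than sampling noise: the chi-square per degree of freedom between replicates was 10.3 to 23.2 in the ROI and 10.0 to 36.9 outside it, so no pair was treated as a duplicate. UMIs are counted molecules, and all intervals below cover counting error only.

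Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, TMM scaling, filterByExpr with a count minimum of 10) and Benjamini-Hochberg adjustment, with a threshold of 0.05. One fit took the 8 ROI libraries with a group term (12938 genes, 4 residual degrees of freedom) and another the 8 libraries from outside the ROI (14086 genes, 4 residual degrees of freedom). The last took all 16 libraries with a term for each section, so that the ROI was compared with the rest of its own section at each time, and tested whether that contrast differed between each injured time and D0 (14250 genes). The fold changes are fitted log2 values with their standard errors (SE), and levels are counts per 1e6 UMIs (CPM, TMM-scaled) as mean ± SD over 2 sections. Where the D0 ROIs together held no count of a gene, the ratio is a lower bound against a floor of 3 counts over the group, and where they held 1 to 3 counts it is the ratio of summed counts with its 95% counting interval (exact binomial).

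Before the data were examined, 38 gene lists for cell types, pathways and neighbouring tissues were fixed, with 656 genes of which 653 were among the features; cytosolic ribosomal protein genes formed a 39th. Lists with at least 3 measured members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with a correlation estimated from the data, adjusted over the lists of a comparison. The fits, the alternatives and the rule for named genes were fixed at the same point. The rule took genes past the threshold whose groups did not overlap and whose average log2 CPM was at least 5, leaving out predicted, mitochondrial and ribosomal protein genes: the 7 with the largest change in each direction (5 for the comparisons outside the ROI, between injured times and of the difference), up to 4 members with the smallest p of each list called by camera, and a fixed panel of 12 genes in each ROI comparison with D0. Genes named outside this rule are said to be so. The near-identical replication-dependent histone genes, of which Hist1h4h is one, share reads, so its values are uncertain. Co-location of gene lists was measured as Spearman's rho across the ROI spots with at least 200 UMIs in each section, between the shares of UMIs that 2 lists took, with genes held by both lists left out, and tested over the 6 injured sections with an exact 2-sided sign-flip test (64 sign patterns, smallest possible p 0.0312), with 8 pairs of lists in one family and 5 lists against the reporter in another.

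The ROI fit, the fit of all 16 libraries, the list test and the co-location test were tested on simulated data with the real library sizes and means. The fit outside the ROI was not simulated. In the fits, changes were put only into genes above a minimum mean level in the ROI, and all genes were given the same relative spread. Recovery of lower or more variable genes was therefore not measured. For D14 against D0 in the ROI (12774 genes), 13.2% of genes changed 2-fold, 75.4% of those changed 4-fold and 100% of those changed 8-fold were recovered, with 4 false among 128 calls. For D28 against D21 (12806 genes) the shares were 17.6%, 95.7% and 100%, with 7 false among 148 calls. For the ROI against the rest at D14 (14033 genes) they were 86.8%, 100% and 100%, with 10 false among 201 calls, and for the difference of that contrast between D14 and D0 (14051 genes) 30.9%, 82.6% and 98.4%, with 5 false among 145 calls. A raised list was called in the simulated D14 comparison at adjusted p = 5.53e-31, and at 0.00673 with an estimated correlation, with 0 other lists called of 39. The simulated genes varied independently of each other, so this could not test whether the preset correlation suits the real lists. The co-location test gave a mean rho of 0.688 (exact p = 0.031) for simulated lists that shared a spot factor and 0.020 (exact p = 0.469) for independent lists, over 6 sections.

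The alternatives were size factors of the DESeq2 kind (RLE) or library totals alone as scaling, DESeq2 1.42.0 as the test, no filter on low counts, removal of the skeletal muscle list genes, thinning of each library to the smallest total, the replicate number as a block, a fit of only the 2 groups compared, the rest of the section without spots within 3 array steps of the ROI, for co-location thinning each spot to 500 UMIs or a partial correlation given total UMIs, and leaving out each section in turn. DESeq2 was run on all features with its own scaling and filter, so its counts differ from those of edgeR by more than the test. When a left-out section leaves a group with 1 section, that section is assumed to vary like the other groups. A term for the Space Ranger version and a term for sex, read from Xist and Y-linked transcripts, were added after the data were seen. Tables and figures were made in Python 3.11.15 with numpy, scipy, pandas and matplotlib.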

Results

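Spatial gene expression was measured in sections of mouse hindpaw during healing of the flexor digitorum longus (FDL) tendon, a tendon that bends the toes. In the 10x Visium assay a tissue section lies on an array of barcoded capture spots, each of which can hold several cells and yields a count of unique molecular identifiers (UMIs) per gene. The mice, 10 to 12 weeks old, carried Scx-CreER, a tamoxifen-dependent recombinase driven by the tendon transcription factor scleraxis, together with the Ai9 reporter. Tamoxifen on days -7 to -4 therefore marked cells that then expressed Scx, and their progeny, with tdTomato. The FDL was cut through and repaired on day 0, and hindpaws were taken without injury (D0) or 14, 21 or 28 days after surgery (D14, D21 and D28), with 2 biological replicates at each of the 4 times. The comparisons address how expression in the healing tendon differs from that of the uninjured tendon and of the surrounding tissue, and where transcripts of the marked lineage lie.

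The 8 sections held 84834772 UMIs in 8465 spots, of which 1537 formed the region of interest (ROI) given by the authors. The ROI held 194530 UMIs in 40 spots in D0 replicate 1 and 751546 in 122 spots in D0 replicate 2. It held 3196235 and 5676281 UMIs in 222 and 363 spots in the D14 replicates, 4570321 and 3210902 in 210 and 196 spots at D21, and 2150363 and 2536016 in 186 and 198 spots at D28. Fast skeletal muscle transcripts took 8.55 ± 2.24% of ROI UMIs at D0 (mean ± SD, n = 2), against 1.63 ± 0.503% at D14, 4.08 ± 1.84% at D21 and 2.48 ± 0.0901% at D28. Mitochondrially encoded transcripts, which are abundant in muscle, took 11.3 ± 4.59% at D0, then 3.29 ± 0.0267%, 4.12 ± 0.86% and 3.75 ± 0.229%. Keratinocyte and skin transcripts took 2.94 ± 2.58% at D0, with most of it in replicate 1, then 0.62 ± 0.214%, 1.11 ± 0.128% and 1.53 ± 0.72%. D0 replicate 1, both D14 replicates and D28 replicate 1 came from Space Ranger 1.1.0 and the other sections from version 1.3.1. Xist, expressed from the inactive X chromosome, was found in D0 replicate 1, both D14 replicates, D21 replicate 1 and D28 replicate 2, and Y-linked transcripts were in D0 replicate 2, D21 replicate 2 and D28 replicate 1. Neither split followed injury, but D14 was seen with 1 version and 1 sex and D21 with 1 version only.

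**Figure D1:**
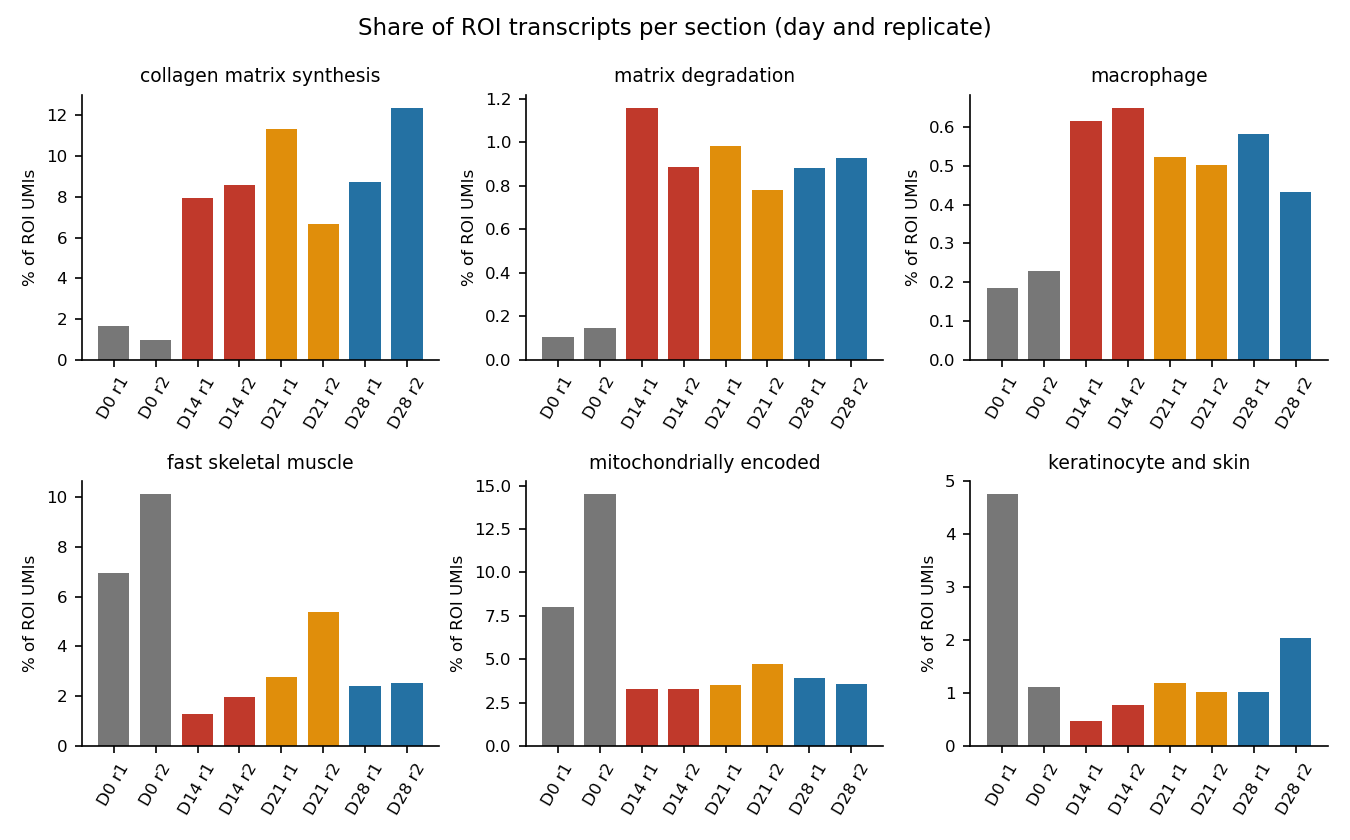
Bars show the percentage of ROI UMIs taken by 6 gene lists in each of the 8 sections, labelled by day and replicate (r). Collagen matrix transcripts took 1.32% on average at D0 and 8.25%, 9% and 10.6% at D14, D21 and D28. The muscle and mitochondrial shares were highest in the D0 sections.

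At D14 collagen matrix genes were higher in the ROI than in the uninjured ROI. Of the 30 collagen matrix synthesis genes, 28 rose and 0 fell (30 rose adjusted over the list alone). Col3a1, the type III collagen of early repair (chromosome 1, 45311538 to 45349706, mm10), rose from 739 ± 48.6 to 11430 ± 679 CPM (log2 change 3.95 ± 0.43 SE, edgeR adjusted p = 0.00137, n = 2 per group). Col1a1 rose 5.22-fold (adjusted p = 0.025, log2 2.39, against 3.18 without D0 replicate 1 and 1.92 without D0 replicate 2). It lost its call in 3 of the 8 fits that left out 1 section. Without D0 replicates 1 and 2 the collagen genes that rose were 25 and 17 of 30. Fn1, the fibronectin that precedes collagen in wounds, rose 17.9-fold (log2 4.16 ± 0.43, adjusted p = 0.00107). Of 20 myofibroblast genes 11 rose and 0 fell (12 adjusted over the list alone), among them the matricellular proteins Postn (30.6-fold, adjusted p = 0.000863) and Tnc (23.8-fold, adjusted p = 0.000863). The contractile actin Acta2 had a log2 change of 0.80 ± 0.39 (adjusted p = 0.199). Cthrc1, a secreted protein of activated fibroblasts, had 1 UMI in both D0 ROIs together, and its ratio to D0 was 659 (95% counting interval 118 to 26000). The metalloprotease Adam12 had no D0 UMI and was at least 34.3-fold higher.

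Genes that remodel matrix and genes of inflammation rose alongside. Of 20 matrix degradation genes 13 rose and 0 fell (13 adjusted over the list alone). The collagenase Mmp13 rose 130-fold (log2 7.02 ± 0.66, adjusted p = 0.000863), Mmp3 100.4-fold (adjusted p = 0.00176), the inhibitor Timp1 71.3-fold (adjusted p = 0.000863) and the osteoclast and macrophage protease Ctsk 23.8-fold (adjusted p = 0.00176). The D0 replicates held 0 and 8 UMIs of Mmp13, 2 and 3 of Mmp3, 4 and 18 of Timp1 and 8 and 27 of Ctsk. Without D0 replicate 2 the log2 change of Mmp13 was 14.89, against no D0 UMI, and 6 of the 20 genes rose. Of 23 macrophage genes 9 rose and 0 fell (13 adjusted over the list alone), including Cd68 (5.81-fold, adjusted p = 0.00499) and Lyz2 (4.06-fold, adjusted p = 0.0098). Of 16 lipid and lysosome macrophage genes 8 rose and Lpl fell, a lipase of fat and muscle as well as of macrophages (9 and 1 adjusted over the list alone). Spp1, osteopontin, rose 6.13-fold (adjusted p = 0.0096). Among 20 inflammatory cytokine genes 7 rose and 0 fell (9 adjusted over the list alone), with the monocyte attractant Ccl12 at least 19.5-fold higher and the neutrophil attractant Cxcl5 at a ratio of 75.4 (13.5 to 2980). Of 10 neutrophil and granule genes 5 rose and 0 fell (5 adjusted over the list alone). S100a8 rose 7.29-fold (adjusted p = 0.00475, 4 and 39 D0 UMIs), S100a9 7.48-fold (adjusted p = 0.0112, 4 and 38 D0 UMIs) and the gelatinase Mmp9 31.1-fold (adjusted p = 0.0148, 0 and 20 D0 UMIs). Of 23 cell cycle genes 9 rose and 0 fell (20 adjusted over the list alone), among them Mki67 (log2 1.59 ± 0.43, adjusted p = 0.0385) and Mcm6 (5.63-fold, adjusted p = 0.0207). Further large ratios came from genes with 1 or 2 D0 UMIs: the cartilage proteoglycan Acan (214, interval 38.3 to 8440), C1qtnf3 (265, 47.6 to 10500), the protease inhibitor Slpi (183, 50.5 to 1510) and the acute-phase protein Saa3 (173, 47.8 to 1430).

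Genes of mature tendon did not move as a group at D14. Of 19 in the list 3 rose and 2 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.724, and adjusted p = 0.905 with an estimated correlation). Thbs4 rose 8.44-fold (adjusted p = 0.00403). Chad, a leucine-rich matrix protein, fell from 1623 ± 272 to 195 ± 35.5 CPM (log2 -3.05 ± 0.35, adjusted p = 0.00167) and Angptl7 fell as well (log2 -2.08 ± 0.31, adjusted p = 0.00403). These last 2 were chosen after their values were seen. The log2 changes of Scx (2.92 ± 0.82, adjusted p = 0.0524), tenomodulin Tnmd (2.03 ± 0.89, adjusted p = 0.177), Mkx (1.26 ± 0.47, adjusted p = 0.106) and fibromodulin Fmod (0.17 ± 0.61, adjusted p = 0.892) did not pass the test. Transcripts typical of muscle, skin and nerve were lower, and so were mitochondrially encoded ones. Of these, 27 of 27 fast muscle genes fell (27 adjusted over the list alone; Acta1 by log2 -2.14 ± 0.51, Atp2a1 by -2.77 ± 0.43). So did 6 of 11 slow muscle genes (8 adjusted over the list alone) and 13 of 13 mitochondrially encoded genes (13 adjusted over the list alone). Without D0 replicate 2 the counts were 7 of 27 fast muscle and 0 of 13 mitochondrial genes, with medians of -2.22 and -1.26 in place of -2.71 and -1.95. They were 21 and 2 with a version term. Of the skin and nerve genes, 10 of 18 keratinocyte genes fell (16 adjusted over the list alone; Krt1 -4.60 ± 0.91, Lce1h -3.46 ± 0.63), and 5 of 14 Schwann and nerve genes (8 adjusted over the list alone; Prx -2.38 ± 0.34). Of 12 regenerating muscle genes 1, Myl4, rose and 0 fell (1 adjusted over the list alone, camera adjusted p = 0.281, and adjusted p = 0.791 with an estimated correlation). Myoc, a secreted glycoprotein, fell by 3.62 ± 0.45, the mitochondrial creatine kinase Ckmt2 fell by 3.48 ± 0.47 and Hist1h4h, one of a family of near-identical histone genes, fell by 3.45 ± 0.36.

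In all, 1517 of 12938 genes passed at D14, 749 higher and 768 lower (edgeR quasi-likelihood, Benjamini-Hochberg). With library totals alone as scaling the split was 990 higher and 584 lower, and the median of all genes then lay at 0.24 on the log2 scale (0.08 with TMM). The camera test called the collagen (adjusted p = 4.72e-43), matrix degradation (5.98e-18), myofibroblast (2.68e-12), macrophage (4.1e-07), lipid macrophage (6.77e-07), cytokine (1.34e-08), neutrophil (0.000131), cell cycle (8.89e-09), fast muscle (6.36e-34), slow muscle (1.69e-08), mitochondrial (5.25e-12), keratinocyte (3.01e-10) and Schwann (0.000404) lists. With an estimated correlation only matrix degradation was called (adjusted p = 0.0278). The adjusted p with an estimated correlation was 0.0545 for collagen, myofibroblast and lipid macrophage, 0.0857 for cytokine, 0.179 for neutrophil and fast muscle, 0.2 for macrophage, 0.259 for slow muscle and mitochondrial, 0.26 for Schwann and 0.27 for cell cycle and keratinocyte. The count was 330 without D0 replicate 2, 268 without D14 replicate 1 and 672 without D14 replicate 2, and 13, 12 and 6 of the 37 named genes past the threshold then lost it. Mki67 lost its call in 6 of the 8 fits that left out 1 section, Mmp9 in 5 and Krt1 in 4. Krt1 was at -2.45 without D0 replicate 1, and the median of the keratinocyte list was then -1.15 in place of -2.33. Against D0 replicate 1, the D0 section of the same Space Ranger version and sex, the median log2 ratio of the collagen list was 2.61 and 2.53 in the D14 sections and that of the fast muscle list -2.52 and -2. With a version term 661 genes passed.

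**Figure D2:**
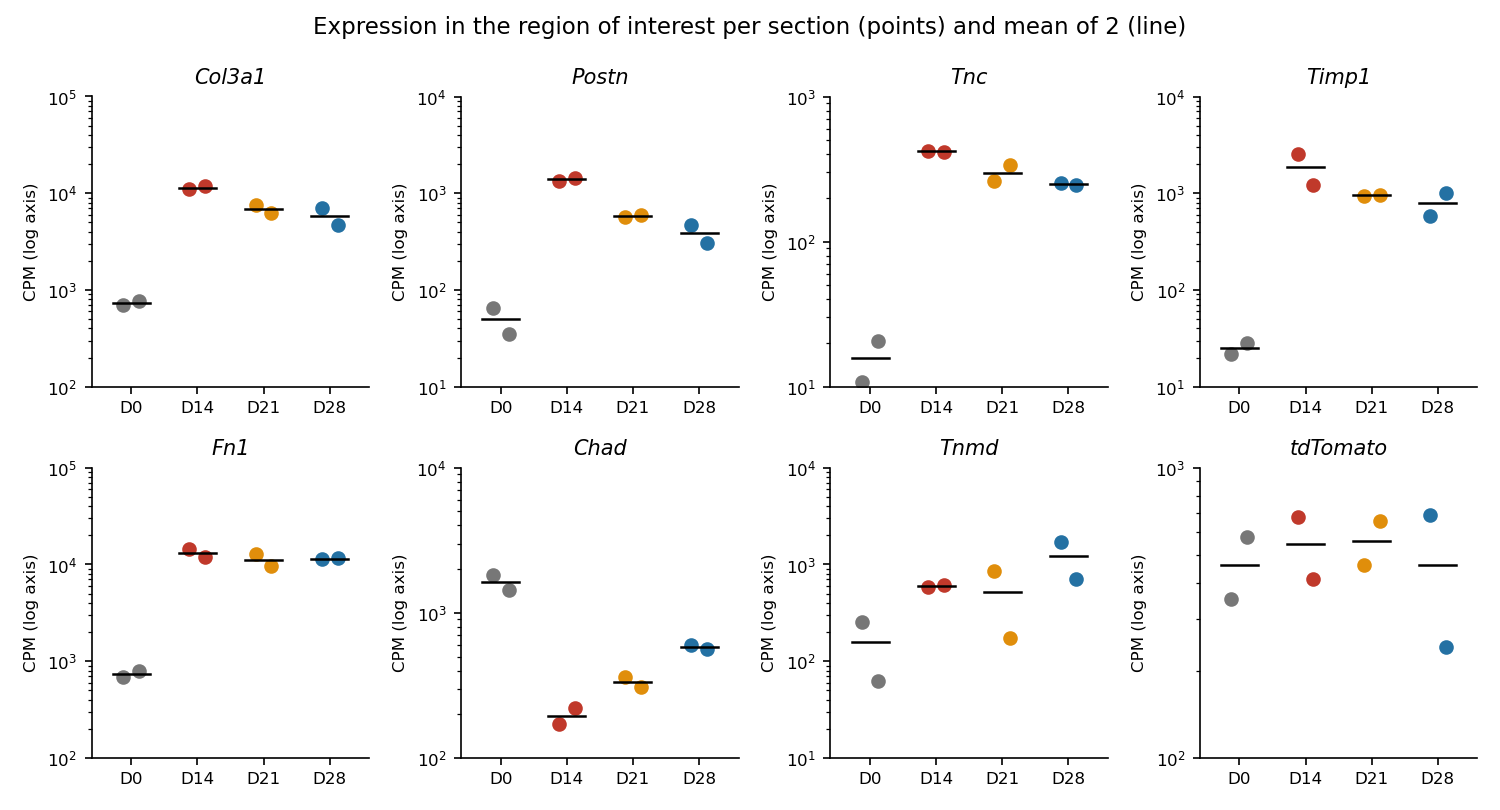
Points show the ROI level of 8 genes in each section in CPM on a log axis, by day, and black lines the mean of 2 sections. Col3a1, Postn, Tnc, Timp1 and Fn1 lay above both D0 sections in each of the 6 injured sections and Chad below. The tdTomato values overlapped between times.

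At D21 the matrix genes were still high. Of 30 collagen matrix genes 20 rose and 0 fell (28 adjusted over the list alone). Without D0 replicate 1 only 2 rose and without D0 replicate 2 none did, although the medians were then 2.10 and 2.22, against 2.21 with all sections. Higher genes were Col3a1 at 9.34-fold (log2 3.22 ± 0.42, adjusted p = 0.00533), Col5a2 at 9.82-fold (adjusted p = 0.00533) and Fn1 at 15.1-fold (adjusted p = 0.00338). Col1a1 had a log2 change of 2.69 ± 0.58 (adjusted p = 0.0515). Of 20 myofibroblast genes 7 rose, among them Postn (12.7-fold, adjusted p = 0.00425) and Tnc (16.9-fold, adjusted p = 0.00281), and the smooth muscle gene Cnn1, chosen after its value was seen, fell (log2 -3.37 ± 0.66, adjusted p = 0.0341; 12 and 2 adjusted over the list alone). Of 20 matrix degradation genes 8 rose and 0 fell (14 adjusted over the list alone), with Mmp13 at 133-fold (adjusted p = 0.00263), Mmp2 at 9.77-fold (adjusted p = 0.00518), Timp1 at 36.1-fold (adjusted p = 0.00331) and Ctsk at 9.27-fold (adjusted p = 0.0169). Mmp13, with 0 and 8 D0 UMIs, ranged from log2 6.62 to 14.93 when 1 section was left out. Of 16 lipid and lysosome macrophage genes 5 rose and 0 fell (8 adjusted over the list alone; Spp1 5.52-fold, adjusted p = 0.0388). Of 23 macrophage genes 0 passed over all genes and 9 rose adjusted over the list alone (Cd68 log2 1.49 ± 0.41, adjusted p = 0.0968). The growth factor Mdk, with 1 UMI in the D0 ROIs, had a ratio of 98.6 (17.6 to 3900), Cthrc1 466 (83.7 to 18400), C1qtnf3 255 (45.8 to 10100) and Acan 101 (18.1 to 4010). Adam12 was at least 30.5-fold higher.

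Among 19 mature tendon genes 2 rose and 2 fell at D21 (3 and 2 adjusted over the list alone, camera adjusted p = 0.442, and adjusted p = 0.748 with an estimated correlation). The lower ones were Chad (log2 -2.28 ± 0.34, adjusted p = 0.0111) and Angptl7 (-2.44 ± 0.32, adjusted p = 0.00537). Scx (1.85 ± 0.85, adjusted p = 0.29), Tnmd (1.82 ± 0.89, adjusted p = 0.321), Mkx (1.39 ± 0.47, adjusted p = 0.154), Fmod (0.24 ± 0.61, adjusted p = 0.882), Acta2 (-0.16 ± 0.38, adjusted p = 0.876), Acta1 (-1.04 ± 0.50, adjusted p = 0.294) and Mki67 (1.46 ± 0.44, adjusted p = 0.114) did not pass. The nuclear noncoding RNA Malat1 (-2.46 ± 0.37), Myoc (-2.09 ± 0.42) and Hist1h4h (-2.41 ± 0.34) fell. Of 27 fast muscle genes 0 passed over all genes and 22 fell adjusted over the list alone. Of 13 mitochondrial genes 0 passed and 12 fell in the same way. By edgeR 184 genes passed, 158 higher and 26 lower. The split was 145 to 100 with libraries thinned to equal totals and 416 to 259 by DESeq2, so the lean to higher genes was smaller there. Camera called the collagen (adjusted p = 2.05e-50), matrix degradation (2.05e-23), myofibroblast (5.62e-11), macrophage (8.16e-07), lipid macrophage (2.62e-08), fast muscle (4.82e-18) and mitochondrial (2.91e-13) lists. With an estimated correlation matrix degradation kept its call (adjusted p = 0.0143), and the adjusted p was 0.0568 for collagen and lipid macrophage, 0.0654 for myofibroblast, 0.288 for macrophage and 0.301 for fast muscle and mitochondrial. The count was 1 without D0 replicate 2, when none of the 21 named genes past the threshold kept it. Of the 8 fits that left out 1 section, Cnn1 and Myoc lost their calls in 6 and Chad, Malat1 and Spp1 in 4. It was 29 without D0 replicate 1, 39 without D21 replicate 1, 122 and 108 without D14 replicates 1 and 2, and 462 and 473 without D28 replicates 1 and 2. Against D0 replicate 2, of the same version, the median log2 ratio of the collagen list was 2.26 and 1.91 in the D21 sections and that of fast muscle -2.23 and -1.38. With a version term 255 genes passed.

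At D28 Col1a1 was 8.21-fold above D0 (27380 ± 9708 against 3342 ± 1985 CPM, log2 3.04 ± 0.59, adjusted p = 0.0255). The log2 change of Col1a1 was 3.84 without D0 replicate 1 and 2.57 without D0 replicate 2. At the same time 26 of 30 collagen matrix genes rose with 0 lower (29 adjusted over the list alone), including Col12a1 (13.4-fold, adjusted p = 0.00365), Col3a1 (7.93-fold, adjusted p = 0.00691) and Fn1 (15.6-fold, adjusted p = 0.00365). Without D0 replicates 1 and 2 the collagen genes that rose were 13 and 0 of 30. Of 20 myofibroblast genes 8 rose and 0 fell (12 and 2 adjusted over the list alone). Postn rose 8.45-fold (adjusted p = 0.0073) and Tnc 14.2-fold (adjusted p = 0.00365). Of 20 matrix degradation genes 9 rose and 0 fell (11 adjusted over the list alone), with Mmp13 at 92.7-fold, Mmp2 at 11.3-fold and Timp1 at 30.3-fold (each adjusted p = 0.00365). Mmp13 ranged from log2 6.10 to 14.40 when 1 section was left out, given its 0 and 8 D0 UMIs. In the mature tendon list Col11a1 (11.4-fold, adjusted p = 0.012) and Thbs4 (8.34-fold, adjusted p = 0.0106) rose and Chad fell (log2 -1.47 ± 0.33, adjusted p = 0.0362), of 19 genes (8 and 2 adjusted over the list alone). In the cartilage list Acan (ratio 166, 29.7 to 6570) and Matn4 (54.6, 18.6 to 265) rose, of 12 genes (2 adjusted over the list alone). Cthrc1 (609, 109 to 24000), C1qtnf3 (293, 52.5 to 11600) and Adam12 (at least 17.5-fold) were again far above D0. Tnmd (3.05 ± 0.91, adjusted p = 0.109), Scx (2.63 ± 0.83, adjusted p = 0.121), Mkx (1.86 ± 0.46, adjusted p = 0.051), Fmod (1.04 ± 0.62, adjusted p = 0.377) and Cd68 (1.51 ± 0.41, adjusted p = 0.071) did not pass. Neither did Mki67 (1.21 ± 0.45, adjusted p = 0.157), Acta2 (0.17 ± 0.39, adjusted p = 0.854) and Acta1 (-1.95 ± 0.51, adjusted p = 0.0615). Spp1 rose 6.80-fold (adjusted p = 0.0202).

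Of 27 fast muscle genes 19 fell at D28 (27 adjusted over the list alone; Myh4 -3.50 ± 0.70, Tnni2 -2.57 ± 0.49). That number was 12 without D0 replicate 1 and 0 without D0 replicate 2, with medians of -2.45 and -1.58 in place of -2.08. Also lower were 6 of 13 mitochondrial genes (13 adjusted over the list alone) and 10 of 37 nuclear oxidative phosphorylation genes (35 adjusted over the list alone), among them the muscle form Cox7a1 (-2.72 ± 0.50, adjusted p = 0.0218). Hist1h4h fell as well (-3.00 ± 0.36, adjusted p = 0.00365). Of 23 macrophage genes 1, Ms4a7, rose (9 adjusted over the list alone). By edgeR 498 genes passed, 266 higher and 232 lower. With library totals alone the split was 568 to 154. The median of all genes then lay at 0.34 on the log2 scale. By DESeq2 430 were higher and 460 lower, and with thinned libraries 186 and 215. Camera called the collagen (adjusted p = 3.29e-49), myofibroblast (5.76e-12), matrix degradation (8.87e-18), macrophage (1.16e-05), mature tendon (7.03e-05), cartilage (0.00277), fast muscle (1.45e-32), mitochondrial (9.89e-15) and oxidative phosphorylation (2.78e-24) lists. With an estimated correlation matrix degradation kept its call (adjusted p = 0.025), and the adjusted p was 0.0517 for collagen and myofibroblast, 0.244 for fast muscle, 0.262 for macrophage, cartilage and mitochondrial, 0.288 for oxidative phosphorylation and 0.325 for mature tendon. Chad lost its call whichever of the 8 sections was left out, and Myh4 and Matn4 in 4 of 8. Without D0 replicate 2 the count was 0 by edgeR and none of the 22 named genes past the threshold kept it, although the median log2 change of the collagen list was then 2.48. The counts were 240 without D0 replicate 1, 307 and 264 without D14 replicates 1 and 2, and 308 without D28 replicate 2. Against the D0 section of the same version the median log2 ratio of the collagen list was 2.20 and 2.39 in the D28 sections and that of fast muscle -1.66 and -2.34. With a version term 616 genes passed.

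From D14 to D21 in the ROI, 9 genes fell and 1 rose. With only these 2 groups in the fit 1240 genes passed, 580 higher and 660 lower. Saa3 fell from 386 ± 70.2 to 1.34 ± 1.89 CPM (log2 -7.96 ± 0.71, adjusted p = 0.00238) and Cxcl5 from 83.3 ± 10.7 to 1.87 ± 1.43 (adjusted p = 0.00157). The neutrophil proteins S100a8 (log2 -3.73 ± 0.42, adjusted p = 0.00705) and S100a9 (-4.19 ± 0.53, adjusted p = 0.0221) and haptoglobin Hp (-3.23 ± 0.39, adjusted p = 0.0108) fell too. The other 5 of the 10 genes, chosen after their values were seen, were Tnn (-4.37 ± 0.35), Ptx3 (-2.80 ± 0.40), Steap1 (-3.07 ± 0.42) and Mt3 (-3.00 ± 0.44), which fell, and the skin keratin Krt77, which rose from 0.0872 ± 0.123 to 41.3 ± 1.61 CPM. Of 10 neutrophil genes 2 fell (8 adjusted over the list alone, camera adjusted p = 1.5e-16, and adjusted p = 0.162 with an estimated correlation). Of 23 cell cycle genes 0 passed over all genes and 13 fell adjusted over the list alone (camera adjusted p = 5.52e-12, and adjusted p = 0.366 with an estimated correlation). Ptx3 and Mt3 lost their calls in 6 of the 8 fits that left out 1 section, Krt77 in 5 and Steap1 in 4. The count of 10 was 6 without D0 replicate 1, 4 and 27 without D21 replicates 1 and 2, and 227 and 233 without D28 replicates 1 and 2. Without D21 replicate 2 the split was 21 higher and 6 lower, with a sex term 62 and 35, with no filter on low counts 591 and 431, and by DESeq2 72 and 119, so the balance of higher and lower genes was not settled. D14 and D21 share no Space Ranger version. With a version term 1 gene passed, which was higher, so each of the 9 falls lost its call.

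From D21 to D28 0 genes passed by edgeR (297 at an unadjusted p under 0.05; 3 by DESeq2). From D14 to D28 0 passed (1652 unadjusted; 75 by DESeq2). The mature tendon list lay higher at D28 than at D21 in 18 of 19 genes (0 past the threshold over all genes, 1 higher adjusted over the list alone, camera adjusted p = 2.57e-11, and adjusted p = 0.454 with an estimated correlation). It lay higher than at D14 in 14 of 19 (0 over all genes, 6 adjusted over the list alone, camera adjusted p = 6.62e-06, and adjusted p = 0.443 with an estimated correlation). The interferon response list lay lower at D28 than at D21 in 17 of 17 genes (0 over all genes, 8 adjusted over the list alone, camera adjusted p = 1.56e-16, and adjusted p = 0.454 with an estimated correlation). Of 10 neutrophil genes 7 were lower at D28 than at D14 adjusted over the list alone (camera adjusted p = 1.61e-10, and adjusted p = 0.324 with an estimated correlation). Counts without 1 section were 3 without D21 replicate 2 and 1 without either D28 replicate for D28 against D21. For D28 against D14 they were 2 without D14 replicate 1, 10 and 9 without D21 replicates 1 and 2, and 422 and 3 without D28 replicates 1 and 2.

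Outside the ROI the same kinds of matrix genes were higher after injury. Fast muscle transcripts took 10.0 ± 1.44% of UMIs there at D0 and 6.34 ± 0.866%, 6.57 ± 0.338% and 5.92 ± 0.53% at D14, D21 and D28. Mitochondrially encoded transcripts took 11.2 ± 0.76% there at D0, then 7.49 ± 1.59%, 6.58 ± 0.241% and 6.32 ± 0.508%. At D14 27 of 30 collagen matrix genes rose and 0 fell (30 adjusted over the list alone). Cthrc1 rose from 2.65 ± 0.527 to 255 ± 69.9 CPM (log2 6.71 ± 0.43, adjusted p = 0.000688). C1qtnf3 (43.3-fold, adjusted p = 0.00752), Mmp13 (27.1-fold, adjusted p = 0.0031), Postn (12.9-fold, adjusted p = 0.0043), Tnc (10.7-fold, adjusted p = 0.00152) and Fn1 (8.23-fold, adjusted p = 0.00585) rose. Of 21 matrix degradation genes 8 rose (15, with 1 lower, adjusted over the list alone), of 20 myofibroblast genes 7 (9 adjusted over the list alone), of 22 cytokine genes 4 (9 adjusted over the list alone) and of 16 regenerating muscle genes 4 (6 adjusted over the list alone). The last included the perinatal myosin Myh8 (11.1-fold, adjusted p = 0.00752) and myogenin Myog (4.91-fold, adjusted p = 0.033). The muscle enzyme Ampd1 (log2 -1.46 ± 0.24, adjusted p = 0.0185) and the sebaceous keratin Krt79 (-2.03 ± 0.33, adjusted p = 0.0163) fell. Cthrc1, Mmp13 and Fn1 also rose at D21 (33.8-fold, 24.5-fold and 5.31-fold) and at D28 (45.4-fold, 16.6-fold and 5.16-fold), with Tnc at D21 (5.11-fold) and C1qtnf3 at D28 (24.9-fold). Chrne, a subunit of the muscle acetylcholine receptor, fell at D28 (-1.33 ± 0.20). Of the collagen genes 4 of 30 rose at D21 (26 adjusted over the list alone) and 4 at D28 (25).

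Outside the ROI 453 genes passed at D14 (345 higher, 108 lower), 22 at D21 (22 higher, 0 lower) and 23 at D28 (20 higher, 3 lower) by edgeR. DESeq2 gave 515 higher and 278 lower at D14, 234 and 290 at D21, and 185 and 304 at D28, so that its balance at D21 and D28 was the opposite. With library totals alone the splits were 511 to 57 at D14 and 70 to 2 at D28, and the medians of all genes 0.12 and 0.29. With an estimated correlation the collagen list (adjusted p = 0.0443), matrix degradation (0.0443), cytokine (0.0443) and myofibroblast (0.0491) lists were called at D14. Regenerating muscle was not (adjusted p = 0.233, against 7.6e-07 at the preset correlation), and the collagen list was not at D21 (adjusted p = 0.119, against 1.32e-37) or D28 (0.108, against 5.45e-35). Without D0 replicate 2 the counts were 0, 0 and 0, and without D0 replicate 1 162, 1 and 1. Without D14 replicates 1 and 2 they were 42 and 59 at D14, 3 and 3 at D21, and 3 and 3 at D28. Without D21 replicates 1 and 2 they were 230 and 218 at D14 and 12 and 10 at D28, and D21 had 2 without D21 replicate 1. Without D28 replicates 1 and 2 they were 879 and 887, 106 and 115, and 66 and 36. The median log2 ratio of the collagen list to the D0 section of the same version was 1.73 and 1.63 at D14, 1.46 and 1.25 at D21, and 0.99 and 1.2 at D28. When spots within 3 array steps of the ROI were left out, 4, 0 and 0 of the 30 collagen genes rose at D14, D21 and D28, with medians of 1.53, 0.97 and 0.85 in place of 1.83, 1.14 and 1.11. In all, 19, 4 and 2 genes then passed. Of the 8 fits that left out 1 section, Chrne lost its call at D28 in 7, Myog at D14 in 6, Fn1 at D21 and at D28 in 6 each, C1qtnf3 at D28 in 6, Tnc at D21 in 5, and Ampd1 at D14 and Mmp13 at D28 in 4 each.

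Within the uninjured sections 7 genes differed between the ROI and the rest. Fmod, a collagen-binding proteoglycan of tendon, was 2.69-fold higher in the ROI (log2 1.43 ± 0.22, adjusted p = 0.0385, n = 2 sections), tdTomato 2.62-fold (1.39 ± 0.22, adjusted p = 0.0385), the collagen cross-linking enzyme Lox 2.50-fold (adjusted p = 0.046) and Thbs2 2.33-fold (adjusted p = 0.045). The remaining 3 of the 7 genes were Fa2h, a lipid hydroxylase, at -2.32 ± 0.40 (adjusted p = 0.046), and, chosen after their values were seen, Klk1 at 2.68 ± 0.45 (adjusted p = 0.045) and Cnn1 at -2.05 ± 0.36 (adjusted p = 0.046). Of 19 mature tendon genes 2 passed and 13 were higher adjusted over the list alone (camera adjusted p = 5.17e-32, and adjusted p = 0.63 with an estimated correlation). Of 30 collagen genes 1, Lox, was higher (1 adjusted over the list alone, camera adjusted p = 0.000617, and adjusted p = 0.728 with an estimated correlation). Lox lost its call in 7 and Thbs2 in 5 of the 8 fits that left out 1 section. The count of 7 was 0 with a version or sex term, 0 without D28 replicate 1 or 2, 216 without D0 replicate 1 and 41 without D0 replicate 2, where Cnn1 had a log2 difference of 0.075 and Fa2h one of -1.22.

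After injury the ROI differed from the rest of the same sections in many more genes. At D14 Saa3 (6.50-fold, log2 2.70 ± 0.16, adjusted p = 2.55e-07), Slpi (5.96-fold, adjusted p = 5.28e-07), Mmp9 (4.63-fold, adjusted p = 0.000392), Mmp13 (4.13-fold, adjusted p = 5.26e-05), Spp1 (4.25-fold, adjusted p = 0.0317) and the bone-resorption enzymes Acp5 (4.60-fold, adjusted p = 0.0298) and Ctsk (3.29-fold, adjusted p = 2.29e-05) were higher in the ROI. The muscle genes Trdn (-2.96 ± 0.43, adjusted p = 0.0033), Lmod2 (-2.54 ± 0.26, adjusted p = 5.02e-05) and Car3 (-2.51 ± 0.37, adjusted p = 0.000668) were lower. Of 11 osteoclast genes 10 were higher at D14 (10, with 1 lower, adjusted over the list alone) and of 14 neutrophil genes 8 (9 adjusted over the list alone). At D21 Adam12 (4.66-fold, adjusted p = 5.93e-08), Cthrc1 (4.93-fold, adjusted p = 4.33e-07), Mmp13 (4.94-fold, adjusted p = 1.04e-05), Slpi (5.75-fold) and Spp1 (4.72-fold, adjusted p = 0.028) were higher. So were 11 of 17 interferon response genes (15 adjusted over the list alone), among them Isg15 (3.78-fold, adjusted p = 0.000148) and Ifit1 (3.53-fold, adjusted p = 4.46e-05). At D28 Kera (5.19-fold, adjusted p = 9.74e-08), Cthrc1 (5.33-fold, adjusted p = 5.86e-07), Mmp14 (4.83-fold, adjusted p = 5.38e-07), Matn4 (4.78-fold, adjusted p = 1.54e-06) and Acan (4.72-fold, adjusted p = 5.38e-07) were higher, as were Col11a1 (4.30-fold, adjusted p = 2.33e-06), Mkx (3.65-fold, adjusted p = 1.74e-06) and Mmp13 (5.20-fold). Igfbp2 (-2.40 ± 0.50, adjusted p = 0.0204) and the muscle gene Mybpc2 (-2.11 ± 0.24, adjusted p = 1.16e-05) were lower. Of 12 cartilage genes 8 were higher at D28 and 1, Cytl1, lower (8 and 2 adjusted over the list alone). Spp1 lost its call at D14 and at D21 in 6 of the 8 fits that left out 1 section, and Acp5 at D14 and Igfbp2 at D28 in 4.

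By list, 9, 11 and 16 of 19 mature tendon genes were higher in the ROI at D14, D21 and D28 (10, 13 and 19 adjusted over the list alone, with 1 lower at D14). So were 29 of 30 collagen genes at each time (29 adjusted over the list alone), and 13, 15 and 14 of 20 matrix degradation genes (14, 16 and 15 adjusted over the list alone). Of 23 macrophage genes 10, 16 and 17 were higher (13, 18 and 21 adjusted over the list alone), with the scavenger receptor Cd163 lower at D14. Of 20 myofibroblast genes 12 were higher and 1 lower at D21 (13 and 2 adjusted over the list alone). Fast muscle genes were lower in 27, 4 and 26 of 27 (27, 23 and 26 adjusted over the list alone). Camera called each of these lists at the preset correlation, and with an estimated correlation matrix degradation (adjusted p = 0.0321) and myofibroblast (adjusted p = 0.0336) at D21 kept their calls. At D14, D21 and D28 the adjusted p with an estimated correlation was 0.393, 0.291 and 0.264 for mature tendon, 0.234, 0.21 and 0.26 for collagen, 0.27, 0.291 and 0.264 for macrophage, and 0.27, 0.555 and 0.433 for fast muscle. For matrix degradation it was 0.114 at D14 and 0.123 at D28, for neutrophil 0.114 and for osteoclast 0.226 at D14, for interferon 0.471 at D21 and for cartilage 0.264 at D28.

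**Figure D3:**
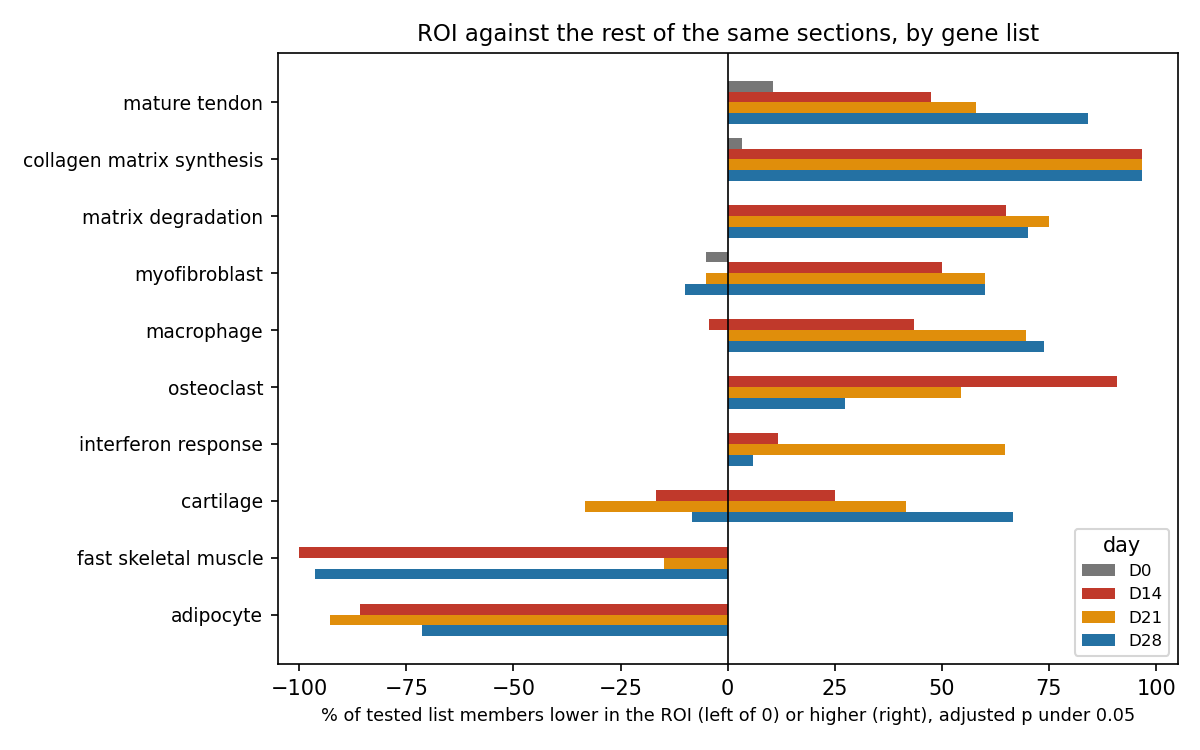
Bars give, for 10 gene lists and 4 times, the percentage of tested members that were higher (right of 0) or lower (left of 0) in the ROI than in the rest of the same sections at an edgeR adjusted p under the threshold. No bar means 0. Collagen genes reach 29 of 30 at each injured time and mature tendon genes 16 of 19 at D28.

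In total 7, 3202, 2726 and 3069 genes differed between the ROI and the rest of the section at D0, D14, D21 and D28 by edgeR. Of these, 1465 were higher and 1737 lower at D14, 1431 and 1295 at D21, and 1509 and 1560 at D28. With library totals alone the splits were 1825 to 1555 at D14 and 1756 to 1351 at D28, and with RLE size factors 1673 to 1637 and 1627 to 1415. The balance at these times therefore depended on the scaling. With libraries thinned to equal totals 4, 344, 148 and 370 genes differed, and the D0 ROIs had the lowest totals. The injured times come from separate sections, and of the genes higher in the ROI 901 were shared by D14 and D21, 880 by D14 and D28 and 1013 by D21 and D28, where independent lists would share 147.1, 155.1 and 151.5. For lower genes the shared numbers were 795, 1008 and 855 against 157.9, 190.2 and 141.8. All times shared 1 fit and 1 estimate of the spread, so full independence could not hold. The excess by itself therefore does not show an effect of injury. The D14 count was 937 and 1311 without D14 replicates 1 and 2, and the D21 count 425 without D21 replicate 1. The D28 count was 812 and 889 without D28 replicates 1 and 2. With a version term they were 3096, 52 and 1254.

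Whether the ROI rose over its surroundings by more after injury than before was tested as the difference of these contrasts. At D14 Myh4, the fastest muscle myosin, fell in the ROI relative to the rest by log2 -2.71 ± 0.30 (adjusted p = 0.000735) and Cpt1b, which brings fatty acids into mitochondria, by -2.40 ± 0.38 (adjusted p = 0.017). Ccl8 (2.57 ± 0.42, adjusted p = 0.0154; 1 and 15 D0 ROI UMIs) and Hp (2.96 ± 0.59, adjusted p = 0.0485; 0 and 11) rose. At D21 Timp1 (2.63 ± 0.37, adjusted p = 0.00443; 4 and 18 UMIs), Csrp2 (2.97 ± 0.43, adjusted p = 0.00443; 5 and 4), Spon1 (2.60 ± 0.39, adjusted p = 0.00602; 1 and 9) and Mmp23 (2.57 ± 0.53, adjusted p = 0.0456; 4 and 2) rose. At D28 Spon1 (2.75 ± 0.39, adjusted p = 0.00896), Crispld2 (2.63 ± 0.39, adjusted p = 0.00896; 6 and 31), Csrp2 (2.80 ± 0.43, adjusted p = 0.0111) and Mmp23 (2.63 ± 0.54, adjusted p = 0.0428) rose and Mybpc2 fell (-2.05 ± 0.35, adjusted p = 0.0165). Of 30 collagen genes 0, 3 and 4 rose at D14, D21 and D28 (12, 15 and 24 adjusted over the list alone; adjusted p = 0.378, 0.21 and 0.188 with an estimated correlation, against 5.03e-11, 2.17e-24 and 5.02e-26). Of 20 matrix degradation genes 4 rose at D21 (11 adjusted over the list alone; adjusted p = 0.0362 with an estimated correlation) and of 20 myofibroblast genes 3 at D21 (9 adjusted over the list alone; adjusted p = 0.0476 with an estimated correlation). Of 27 fast muscle genes 9 fell at D14 (27 adjusted over the list alone, camera adjusted p = 5.93e-31, and adjusted p = 0.336 with an estimated correlation).

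By edgeR the difference passed for 116 genes at D14 (28 higher, 88 lower), 50 at D21 (33 and 17) and 41 at D28 (36 and 5). With the spots near the ROI left out the splits were 38 to 49 at D14 and 18 to 16 at D21. With libraries thinned to equal totals 9, 7 and 2 genes passed, with 2 higher and 5 lower at D21. Without D0 replicate 2 the splits were 80 higher to 298 lower at D21 and 116 to 300 at D28, the opposite balance. Without D0 replicate 1 they were 47 to 35 and 54 to 54. Hp lost its call at D14 in 4 of the 8 fits that left out 1 section. The D14 count was 531 and 295 without D0 replicates 1 and 2, 1 and 248 without D14 replicates 1 and 2, 231 and 242 without D21 replicates 1 and 2, and 49 and 48 without D28 replicates 1 and 2. The D21 count was 82 and 378 without D0 replicates 1 and 2, and 0 and 30 without D21 replicates 1 and 2. The D28 count was 108 and 416 without D0 replicates 1 and 2, and 0 and 4 without D28 replicates 1 and 2. With a version term the counts were 7, 41 and 46.

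The reporter, named here after its values were seen, was higher in the ROI than in the rest of the section at each time. Its D0 call (2.62-fold, edgeR adjusted p = 0.0385) was lost with a version or a sex term, when 0 genes passed. Its level in the ROI was 464 ± 158 CPM at D0, 546 ± 188 at D14, 559 ± 138 at D21 and 463 ± 314 at D28 (n = 2). No injured time differed from D0 for tdTomato (log2 0.22 ± 0.50, 0.25 ± 0.50 and -0.02 ± 0.50; edgeR adjusted p = 0.815, 0.843 and 0.997). Against the rest of the section tdTomato was 2.48-fold higher at D14 (log2 1.31 ± 0.20, adjusted p = 0.000185), 3.04-fold at D21 (1.60 ± 0.20, adjusted p = 2.28e-05) and 3.53-fold at D28 (1.82 ± 0.20, adjusted p = 9.34e-06). The difference of this contrast from D0 did not pass (adjusted p = 0.938, 0.853 and 0.611). Across the ROI spots of the 6 injured sections tdTomato followed the mature tendon list with a mean Spearman rho of 0.497 (SD 0.0801, positive in 6 of 6, exact p = 0.0312, adjusted p = 0.0521) and the collagen list with 0.377 (SD 0.154, 6 of 6, exact p = 0.0312, adjusted p = 0.0521). It ran against fast muscle (-0.248, SD 0.266, positive in 0 of 6, exact p = 0.0312, adjusted p = 0.0521). Its rho with the macrophage list was 0.142 (SD 0.177, 5 of 6, exact p = 0.0938, adjusted p = 0.117) and with the myofibroblast list 0.155 (SD 0.285, 3 of 6, exact p = 0.438, adjusted p = 0.438). No random lists were set beside the reporter, so whether 0 is the right baseline for these values was not tested. Thinned to 500 UMIs per spot the mean rho was 0.129 with mature tendon, 0.102 with collagen and -0.113 with fast muscle. Given total UMIs it was 0.476, 0.33 and -0.2, the last positive in 1 of 6 sections (exact p = 0.0625). The smallest exact p that 6 sections allow is 0.0312, so 5 tests could pass the threshold only if at least 4 reached it.

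**Figure D4:**
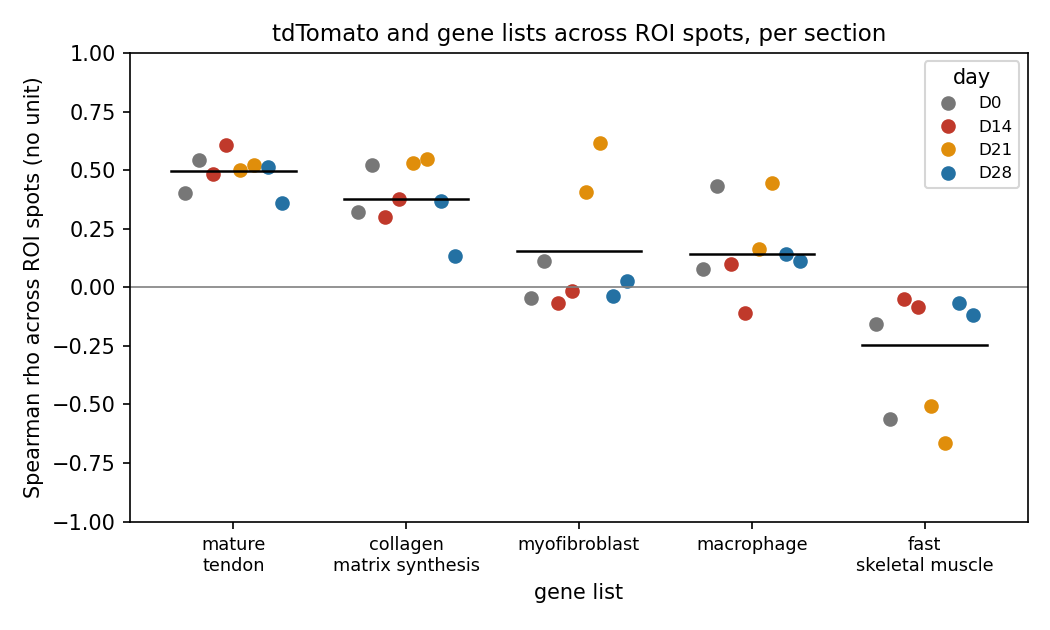
Points show Spearman's rho between the tdTomato share and the share of 5 gene lists across the ROI spots of each section, coloured by day, and black lines the mean over the 6 injured sections. The mature tendon values are above 0 in all 8 sections and those of fast muscle below 0.

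Among pairs of gene lists within the injured ROI, mature tendon and collagen genes had the highest mean rho (0.687, SD 0.119, 6 of 6 sections, exact p = 0.0312, adjusted p = 0.125). It lay at percentile 94.5 of 200 random pairs of lists matched on expression, inside their central 95% (-0.37 to 0.735). Myofibroblast and endothelial genes had a lower mean rho (0.241, SD 0.109, 6 of 6, exact p = 0.0312, adjusted p = 0.125), above each of the 200 random pairs. Thinned to 500 UMIs per spot the mean rho was 0.462 for the first pair and -0.044 for the second, with few endothelial UMIs left per spot. Given total UMIs it was 0.67 and 0.233. The mature tendon list had a low mean rho with macrophage (0.0057, SD 0.236, 1 of 6 positive, exact p = 1) or myofibroblast genes (0.118, SD 0.301, 3 of 6, exact p = 0.375), as did collagen with macrophage genes (-0.0079, SD 0.354, 3 of 6, exact p = 0.969). Macrophage and matrix degradation genes had 0.207 (SD 0.258, 5 of 6, exact p = 0.125), myofibroblast and macrophage genes 0.121 (SD 0.324, 4 of 6, exact p = 0.438), and mature tendon and fast muscle genes -0.278 (SD 0.3, 1 of 6, exact p = 0.125). In the ROIs of D0 replicates 1 and 2 mature tendon with collagen genes had a rho of 0.83 and 0.91. Mature tendon with macrophage genes had 0.51 and 0.62 there, and collagen with macrophage genes 0.54 and 0.64. The difference from D0 was not tested. None of the 8 pairs passed after adjustment, which 6 sections allow only if at least 6 pairs reach the smallest p.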

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

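The tests of dilution by muscle, of surrounding tissue in the uninjured ROI, of tissue next to the ROI as the whole cause and of the reporter were chosen only after the results they bear on were seen. So was the use of the single D14 sections to weigh how much tissue next to the ROI added. The difference between the ROI and the rest of the section changed from D0 for 116 genes at D14, 50 at D21 and 41 at D28 (edgeR, Benjamini-Hochberg adjusted p), and each count was singled out because it is a tested difference of a region effect between groups.

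Collagen matrix genes were higher in the ROI after injury, with a median log2 change of 2.47 over 30 genes at D14. If less muscle had raised the share of each other transcript, the endothelial, adipocyte, Schwann and pericyte lists would have risen by as much. The highest of their medians was -0.25 (0.77 against 2.65 for collagen without D0 replicate 2). This bears on dilution by muscle alone. Adipocyte and Schwann transcripts are also of tissue around the tendon, so a D0 ROI with more surrounding tissue of several kinds could not be excluded. With the libraries thinned to equal totals the collagen median was 2.32, so the lower depth of the D0 ROIs did not produce it. Against the D0 section of the same Space Ranger version the lowest of 6 medians was 1.91, which leaves out the version as the cause. The injury in the design remains as a biological explanation, with 2 sections per time and no sham surgery to part cutting the tendon from the operation. A different tissue make-up of the D0 ROI also remains, since how the ROI was drawn is not given, and it was not tested for the collagen rise.

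Collagen matrix genes were also higher outside the ROI, where the lowest of 6 medians within a Space Ranger version was 0.99, so the version does not account for it. Without spots within 3 array steps of the ROI the lowest of 6 lower quartiles within a version was still 0.32 (0.06 when matched by sex), which excludes tissue that close to the ROI as the whole cause. How much it added stayed open. The D14 median was 0.84 of its former value, past the bound of 0.8 set beforehand. But the 2 D14 sections alone, each against D0 replicate 1, gave 0.73 and 0.79. To weigh these 2 values as well was decided after they were seen. The collagen genes that passed went from 27 to 4 at D14, as the median log2 change went from 1.83 to 1.53 and the median SE from 0.27 to 0.30. A reaction of the paw beyond the tendon may add to the rise, but the design holds no test of it. Fast muscle and mitochondrial genes fell outside the ROI, with section medians within a version of -1.28 to -0.67 and -1.33 to -0.42. Whether a change in the tissue held by the sections adds to the collagen rise there was not tested.

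Fast muscle and mitochondrial genes were lower in the ROI after injury. At D14, D21 and D28, 27, 0 and 19 of 27 fast muscle genes and 13, 0 and 6 of 13 mitochondrial genes passed over all genes. The skin genes passed only at D14, and their share was high in D0 replicate 1 alone (4.76% of ROI UMIs, against 1.12% in replicate 2). In the D0 sections the fast muscle list differed between the ROI and the rest by a pooled median log2 of -0.27, but the sections went opposite ways, with -0.79 in replicate 1 and 0.21 in replicate 2, and the skin list with 1.09 and -1.32. Whether surrounding tissue in the uninjured ROI accounts for the fall inside the ROI could therefore not be told from 2 sections. The fast muscle and mitochondrial lists also fell outside the ROI, with section medians within a version of -1.28 to -0.67 and -1.33 to -0.42. Tissue held in the uninjured ROI would not produce that smaller fall. Against the D0 section of the same Space Ranger version the highest of 6 medians of the fast muscle list in the ROI was -1.38, which leaves out the version for that list. A loss of these transcripts from tendon cells was not tested.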

How the results depend on the processing

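With 2 sections per group the counts of genes depended on single sections. The named genes that passed kept their direction in all but 1 case. The rule for the largest changes took genes whose groups did not overlap, which largely fixes this in advance, so it is no sign of stability. In simulated data 13.2% of genes changed 2-fold between D14 and D0 in the ROI were recovered and 75.4% of those changed 4-fold. These were genes above a minimum mean level, so small changes were mostly out of reach. The Space Ranger version and sex terms were added after the data were seen. D14 was seen with 1 version and 1 sex. Where a count moved, the cause was not tested.

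Without a filter on low counts the ROI counts were 2590, 1152 and 1464 at D14, D21 and D28 against D0, 1022 for D21 against D14, 136 for D28 against D21 and 616 for D28 against D14. Outside the ROI they were 842, 260 and 252, for the ROI against the rest at D0 63, and for the change of that difference from D0 728, 303 and 440 at D14, D21 and D28. DESeq2 gave 675 and 890 for the ROI at D21 and D28 against D0, 191, 3 and 75 for D21 against D14, D28 against D21 and D28 against D14, and 793, 524 and 489 outside the ROI. It gave 27 and 1431 for the ROI against the rest at D0 and D21, and 288, 85 and 111 for the change of that difference. With library totals only as scaling the counts were 537 for the ROI at D21, 242 and 72 outside the ROI at D21 and D28, 15 for the ROI against the rest at D0, and 260 and 72 for its change at D14 and D28. RLE size factors gave 9 outside the ROI at D28.

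Thinned to equal totals, the counts were 746 for the ROI at D14 against D0, 3 for D21 against D14, 5 for D28 against D14, and 39 and 50 outside the ROI at D21 and D28. For the ROI against the rest they were 4, 344, 148 and 370 at D0, D14, D21 and D28, and for its change 9, 7 and 2. With only the 2 groups compared in the fit they were 80 and 146 for the ROI at D21 and D28, 1240 for D21 against D14 and 3 for D28 against D14. With a Space Ranger version term they were 661 for the ROI at D14, 1 for D21 against D14, 1 for D28 against D21, and 61 and 198 outside the ROI at D21 and D28. The same term gave 0, 52 and 1254 for the ROI against the rest at D0, D21 and D28 and 7 for its change at D14. With a sex term they were 97 for D21 against D14, 45 for D28 against D14, 236 and 37 outside the ROI at D14 and D28, 0 for the ROI against the rest at D0 and 9 for its change at D14. Removing muscle genes moved no count by more than 1.5 times. Leaving spots near the ROI out of the rest moved no count of the ROI against the rest or of its change by more, but outside the ROI it took the counts from 453 to 19 at D14, 22 to 4 at D21 and 23 to 2 at D28.

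A replicate block treats replicates of the same number as a pair. The check correlations between groups were 0.053, 0.369, 0.202, 0.013, 0.152 and -0.045. No reference was set for such values, so they neither show nor exclude pairing. The labels name only biological replicates, and the block was not used elsewhere. With the block the counts were 462 and 819 for the ROI at D21 and D28, 350 (220 higher, 130 lower), 10 and 28 for D21 against D14, D28 against D21 and D28 against D14, and 735, 253 and 209 outside the ROI.

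Leaving out 1 section at a time, the counts ranged from 268 to 1884, 1 to 473 and 0 to 502 for the ROI at D14, D21 and D28 against D0. They ranged from 4 to 233 for D21 against D14, 0 to 3 for D28 against D21 and 0 to 422 for D28 against D14. Outside the ROI they ranged from 0 to 887, 0 to 115 and 0 to 66. For the ROI against the rest they ranged from 0 to 216, 937 to 4132, 425 to 3752 and 812 to 3966 at D0, D14, D21 and D28. For the change of that difference they ranged from 1 to 531, 0 to 378 and 0 to 416. Cnn1 in the uninjured ROI against the rest ranged from -2.43 to 0.075, with the sign reversed without D0 replicate 2. None of the 8 co-location pairs passed in any alternative, which 6 sections nearly fix in advance, so the values tell more. Thinned to 500 UMIs per spot, the mean rho went from 0.687 to 0.462 for mature tendon with collagen genes and from 0.241 to -0.044 for myofibroblast with endothelial genes, which then left few endothelial UMIs per spot. Given total UMIs the values were 0.67 and 0.233.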

Other observations

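Adipocyte genes were lower in the ROI than in the rest of the section in 12, 13 and 10 of 14 genes at D14, D21 and D28 by edgeR (13, 14 and 13 adjusted over the list alone), against 0 of 14 at D0 (7 lower adjusted over the list alone). Only 7 of 14250 genes passed at D0 in this contrast, so the 0 there does not show that the adipocyte difference came with injury. Camera gave adjusted p = 4.94e-09, 9.19e-14 and 1.39e-06 at the injured times, and adjusted p = 0.226, 0.226 and 0.341 with an estimated correlation. Of 17 endothelial genes 1, 6 and 4 were higher in the ROI and 1 lower at each of D14, D21 and D28 (1, 8 and 4 higher adjusted over the list alone, with 0, 1 and 1 lower). The camera adjusted p was 0.947, 0.000388 and 0.0072, and adjusted p = 0.988, 0.291 and 0.422 with an estimated correlation. At least 1 tdTomato UMI was found in 73.9 ± 12.6% of ROI spots at D0, 90.7 ± 3.6% at D14, 92.3 ± 1.42% at D21 and 82.5 ± 9.54% at D28 (n = 2 sections), and in 46.4 ± 31.1%, 64.7 ± 0.377%, 70.3 ± 4.95% and 52.2 ± 16.9% of spots outside the ROI, where the depth per spot also differed.

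A hypothesis formed after the values were seen was that tdTomato transcripts lie more with mature tendon genes than with macrophage genes inside the injured ROI. The mean difference of the 2 rank correlations was 0.355 (SD 0.209), above 0 in 6 of 6 sections. The correlations tested were those that prompted the hypothesis, so they could have excluded it but do not bear it out, and it stays open. Thinned to 500 UMIs per spot, the mean rho of tdTomato was 0.129 with mature tendon genes and -0.0333 with macrophage genes. A spot holds several cells, and which cells made tdTomato was not resolved.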
